A study of Mus musculus with 8 samples.

How the data were processed

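RNA-seq was analysed for 8 libraries of primary mouse oligodendrocyte progenitors, 4 treated with a control adenovirus and 4 with an adenovirus carrying Cre recombinase. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, only RNA with an integrity number of at least 8 was used, and libraries were made from oligo-dT captured, fragmented mRNA with random priming. Per the submitters' processing notes, Partek, cutadapt, STAR and DESeq2 were used with the mm10 genome. Their versions, the gene annotation used for counting and whether counting used the strand are not given in the sources used here. The deposited table holds estimated counts per gene that are not normalized, and 52% of its values are not whole numbers. Expected counts that are not whole can arise where reads are divided among features, so genes that share sequence or overlap can exchange counts. The table lists 24155 genes, and no gene has a total under 10 over the 8 libraries. Coordinates and biotypes are those of the deposited table in mm10, with the end given as the last base.

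Columns were matched to samples by the batch names in the labels, and groups were taken from the sample titles. Expected counts were rounded to whole numbers. No gene, library or column was left out before filtering. Genes were kept by edgeR's filterByExpr on group with a minimum count of 10, which left 18102 genes and removed 6053. Library sizes were scaled by TMM factors, dispersions were estimated, and group was tested with glmQLFit (robust) and glmQLFTest, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors were taken from the log2 fold change and its F statistic. CPM values are counts scaled by the TMM-adjusted library size to the usual CPM unit, and log2 CPM used a prior count of 2. Totals ran from 43542742 to 65374488 counts per library, so for genes well above 1 CPM the spread between libraries rather than counting limits precision. Intervals on shares of genes treat genes as independent and do not cover the spread between libraries.

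The main fit, set before the data were examined, had group alone. The fit with the replicate number as a block was set at the same time as the other fit to be run. Batch names in the labels' descriptions give the same number to 1 control and 1 cKO library, so the numbers pair the samples. As a check, deviations from group means correlated at 0.79, 0.79, 0.76 and 0.75 between libraries numbered 1, 3, 4 and 6, against at most 0.39 for a library with any other number of the other group. Because the block changed nearly every call, results are given with it, and group-only values are given for the targeted genes, Serpinb1a, Gpr149 and the list tests. No 2 libraries of a group were duplicates: over 12 pairs within groups, the chi-square per degree of freedom of their counts ran from 49.3 to 228.6.

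Genes were named by a rule set before the data were examined. It took Ehmt1 and Ehmt2, then the 10 higher and 10 lower genes with the largest change among those past the threshold in the group-only fit, changed the same way in all 4 pairs, with a mean of at least 2 CPM and a symbol that is not a model name. Places left over went by the same rule to genes past the threshold with the block, which filled all but Serpinb1a, Ehmt1 and Ehmt2. The rule then took up to 4 members per list with the smallest group-only p. Other list members were named as examples after their values were seen. Some genes that the rule took are not reported here. Gene lists, 30 in all, covered ion channels and receptors, synapse and neuron genes, cell death, oligodendrocyte stages, cholesterol synthesis, cell cycle, stress and signalling, chromatin, imprinted, germline, protocadherin, histone and mitochondrial genes and markers of other cell types. Members absent from the table numbered 80. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists, and again with an estimated correlation and with fry.

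Other settings fixed in advance were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 4 libraries, each library or pair left out, DESeq2 with and without the block, limma-voom, and lists without shared members. Combinations of the block with other scaling, filters, tests, a left-out ribosomal RNA gene other list tests, lists without the targeted genes and level-matched list counts were added after seeing the data. Counts were simulated for 17839 genes from the real means and library sizes with about 200 genes changed. For log2 changes of 0.25, 0.5, 1 and 2, the group-only fit recovered 0%, 4.2%, 34.0% and 66.7% with 0 false calls, and the blocked fit recovered 40.0%, 75.0%, 94.0% and 97.9%. The blocked fit made 29 false calls among 179, or 16.2%, above the nominal rate. In that fit 4.7% of unchanged genes lay under an unadjusted p of 0.05, against 0.1% in the group-only fit. The group-only test was thus conservative in these simulated data. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9 for plots.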

Results

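Polyadenylated RNA was sequenced from primary mouse oligodendrocyte progenitors, the dividing glial cells that give rise to myelinating oligodendrocytes. The cells came from pups at postnatal day 7 carrying loxP-flanked alleles of both Ehmt1 and Ehmt2. They were captured by immunopanning, in which cells bind to antibody-coated dishes, and were grown with PDGF-AA at 10 ng/mL and bFGF at 20 ng/mL. Ehmt1 and Ehmt2 encode partner histone methyltransferases (also called GLP and G9a) that methylate histone H3 on lysine 9. In the cKO group, 4 cultures received an adenovirus carrying red fluorescent protein and Cre recombinase, which recombines the floxed alleles. In the control group, 4 cultures received the virus with the fluorescent protein alone. Virus was applied at a multiplicity of infection of 10 for 6 hours, and RNA was collected at 72 hours after infection. The libraries carry the replicate numbers 1, 3, 4 and 6 in both groups, and each number names a batch that holds 1 control and 1 cKO library. Numbers 2 and 5 were not analysed here. Nothing in the labels says whether batches came from separate animals. Without the replicate block, p-values measure the spread between these samples. With it, they measure the spread between pairs of the difference of cKO from control. Either spread may be partly technical. Total estimated counts per library ran from 43542742 to 65374488, and 18102 genes were tested.

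The first question was whether the targeted genes fell, since this checks the labels. Both did, in all 4 pairs of libraries. Ehmt1 (chromosome 2, 24789928 to 24919614, mm10, minus strand, protein-coding) averaged 95.5 ± 5.58 CPM (counts scaled by library size) in control libraries and 41.5 ± 3.98 CPM in cKO libraries (SD, n = 4 per group). Ehmt2 (chromosome 17, 34898469 to 34914052, plus strand, protein-coding) averaged 177 ± 17.1 CPM in control and 58.4 ± 5.86 CPM in cKO libraries (SD, n = 4 per group). In the edgeR quasi-likelihood fit on group alone, the log2 fold change was -1.20 ± 0.09 (SE) for Ehmt1, with a Benjamini-Hochberg adjusted p of 0.00704. For Ehmt2 it was -1.60 ± 0.11 (SE), with an adjusted p of 0.00471 in the same edgeR test. These levels correspond to 43.4% of control for Ehmt1 and 32.9% for Ehmt2 in the fit with the replicate number as a block. Counts covered whole genes, so reads from exons outside the floxed segments still count, and the remaining level is not a measure of intact transcript. The gene models Gm37139 and Gm38147 overlap Ehmt1 on the same strand. Without control replicate 4 or control replicate 6, the edgeR adjusted p of Ehmt1 in the group-only fit was 0.0503 and 0.0506.

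**Figure D1:**
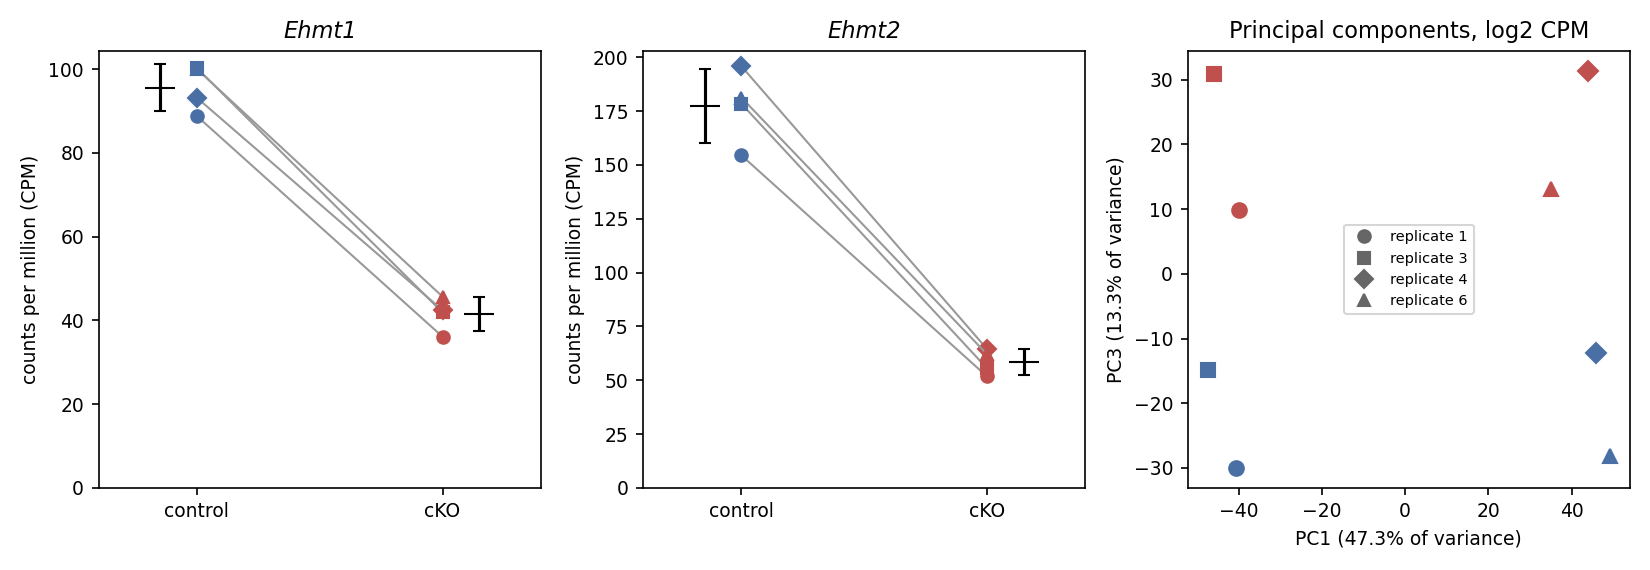
Left and middle, CPM of Ehmt1 and Ehmt2 in each of the 8 libraries, with grey lines joining libraries of the same replicate number and black marks giving the group mean ± SD (n = 4). Right, the libraries on principal components 1 (47.3% of variance) and 3 (13.3%) of log2 CPM, with control in blue, cKO in red and a symbol per replicate number; component 1 parts replicates 1 and 3 from replicates 4 and 6, and component 3 parts the groups.

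The main comparison asked which genes differ between cKO and control progenitors. With group alone in the model, 3 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. Ehmt1 and Ehmt2 fell, and Serpinb1a, which encodes an inhibitor of neutrophil serine proteases, rose from 0.395 ± 0.0843 to 3.64 ± 1.13 CPM (SD, n = 4; log2 fold change 3.20, adjusted p = 0.0232). At an unadjusted p under 0.05 there were 893 genes. Libraries of the same batch varied together, and with the replicate number as a block 3706 genes passed, 1817 higher and 1889 lower in cKO. All 3 genes of the group-only fit were among them. Of the 3706, 3631 moved the same way in all 4 pairs, which passing a fit on pairs favours. Direction varied with the level in control libraries. That level enters the fold change, so grouping by it in itself favours rises at low levels and falls at high levels. Of the genes past the threshold under 1 CPM, 93% were higher (26 were lower), against 70.5% at 1 to 10 CPM (473 higher, 198 lower), 42.4% at 10 to 100 CPM (806 and 1095) and 25.3% over 100 CPM (193 and 570). Most changes were small, with a median absolute log2 fold change of 0.25. Changes of at least 2-fold went mostly upward, in 385 genes against 39. Genes at under 1 CPM in control libraries made up 280 of these 385, and 309 of the 385 were protein-coding.

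**Figure D2:**
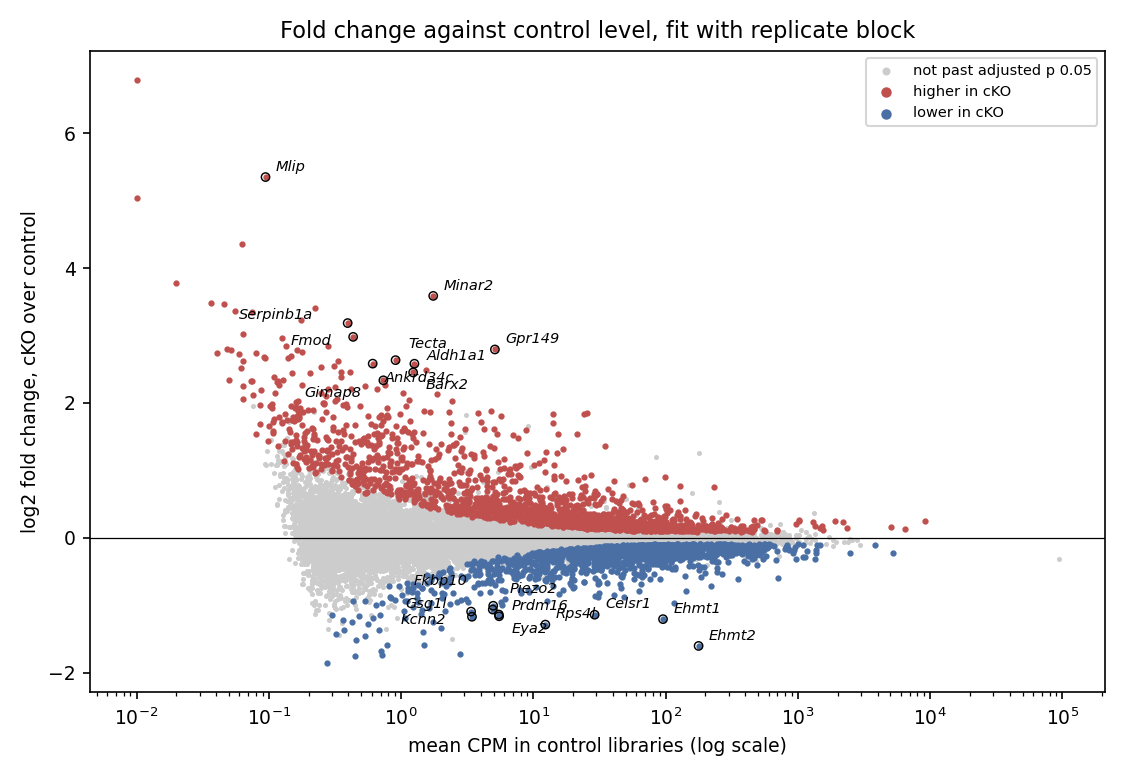
Log2 fold change of cKO over control (vertical axis) against mean control CPM (horizontal axis, log scale) for the 18102 genes tested, from the edgeR fit with the replicate block; control means under 0.01 are drawn at 0.01. Red points are the 1817 genes higher and blue points the 1889 lower in cKO, circles mark the genes named by rule, and changes of at least 2-fold lie mainly upward and at low control levels.

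The count depended on the block and on the libraries. Without the pair of replicate 1, 3 or 4, the blocked edgeR fit called 2367, 2102 and 2118 genes, and without replicate 6 it called 3432. The group-only call of Serpinb1a was lost without any 1 of 7 of the 8 libraries (adjusted p between 0.0644 and 0.139), whereas its blocked adjusted p was 5.5e-06. In simulated data the blocked fit made 29 false calls among 179. As measured facts on the libraries, the share of counts from mitochondrially encoded genes was higher in cKO in all 4 pairs, at 3.32% ± 0.28 against 2.80% ± 0.37 (SD, n = 4). The share taken by CT010467.1, an annotated ribosomal RNA gene, was lower in cKO in all 4 pairs, at 7.67% ± 1.06 against 9.18% ± 0.95. An exact paired permutation test gave p = 0.125 (2-sided) for each, the smallest value that 4 pairs allow.

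Unless another fit is named, values from here on are log2 fold changes of cKO over control ± SE from edgeR's quasi-likelihood fit with the replicate block (4 pairs), and "rose" and "fell" mean past a Benjamini-Hochberg adjusted p of 0.05 in that fit. Among the 10 genes named by rule as highest in cKO, Mlip, a lamin-interacting protein of muscle, rose by 5.35 ± 0.57, from 0.0945 ± 0.135 to 4.15 ± 4.68 CPM (SD, n = 4), with log2 differences within pairs from 1.90 to 7.06. Minar2 rose by 3.59 ± 0.22 (1.75 ± 0.902 to 20.4 ± 4.59 CPM) and Serpinb1a by 3.18 ± 0.19. Fmod, encoding the collagen-binding proteoglycan fibromodulin, rose by 2.98 ± 0.21, from 0.434 ± 0.574 to 3.62 ± 5.14 CPM (SD, n = 4). Its level was 11.3 CPM in cKO replicate 1 and 0.447 CPM in cKO replicate 3. Gpr149, an orphan receptor gene, rose by 2.79 ± 0.07, from 5.12 ± 3.59 to 35 ± 23.3 CPM; its group-only change was 2.77 ± 0.73, with an adjusted p of 0.504. Tecta (2.64 ± 0.22), a tectorial membrane gene of the inner ear, and Ankrd34c (2.58 ± 0.22) also rose. So did Aldh1a1 (2.58 ± 0.22), an enzyme of retinoic acid synthesis, the homeobox gene Barx2 (2.45 ± 0.15) and the immune GTPase gene Gimap8 (2.34 ± 0.21). Control means were low, at 0.908 CPM for Tecta, 0.610 for Ankrd34c, 1.26 for Aldh1a1, 1.23 for Barx2 and 0.735 for Gimap8. Each of these 10 was higher in 4 of 4 pairs, which the naming rule required.

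Fewer genes fell by a like amount. After Ehmt2 and Ehmt1, the genes named by rule as lowest in cKO were led by Rps4l at -1.29 ± 0.09, from 12.3 to 5.10 CPM. Rps4l is annotated as a transcribed processed pseudogene, so its count may include reads of its parent gene, and it lies opposite Tmtc1. Gsg1l, an auxiliary subunit of AMPA-type glutamate receptors, fell (-1.17 ± 0.16), as did the transcriptional cofactor Eya2 (-1.16 ± 0.14). Celsr1, an adhesion receptor of planar cell polarity, fell from 29.1 to 13.7 CPM (-1.14 ± 0.08). Prdm16, a PR-domain transcription factor, fell likewise (-1.14 ± 0.16). Kcnn2, a calcium-activated potassium channel (-1.09 ± 0.13), Piezo2, a mechanically gated channel (-1.06 ± 0.15), and Fkbp10, a collagen chaperone (-1.01 ± 0.10), completed the set. Each was lower in 4 of 4 pairs, again as the naming rule required. Whether counting used the strand is not given in the sources used here, and Tecta, Aldh1a1, Eya2, Prdm16, Kcnn2 and Fkbp10 overlap genes on the opposite strand, so reads of such partners cannot be told apart. None of these genes except Serpinb1a, Ehmt1 and Ehmt2 passed in the group-only fit.

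More genes of ion channels and ligand-gated receptors rose than fell in cKO. The study's title names excitability and cell death as its themes. That choice may rest on these samples, so the direction of these lists is not taken as independent evidence. Their members were fixed before the data were examined. Of 30 voltage-gated sodium and calcium channel genes tested, 12 rose, 4 fell and 14 did neither (13 rose and 5 fell adjusted over the list alone). Scn7a, an atypical sodium channel, rose by 3.41 ± 0.26 from a low level of 0.224 CPM. Scn3b (0.70 ± 0.04) and Scn2a (0.64 ± 0.06), subunits of neuronal sodium channels, rose at higher levels, Scn2a from 14.4 to 22.5 CPM, while the calcium channel gene Cacna1c fell (-0.21). Of 55 potassium channel genes, 16 rose, 4 fell and 35 did neither (19 and 7 adjusted over the list alone). Kcnj6, an inward rectifier, rose by 1.84 ± 0.21 and Kcnh8 by 1.31 ± 0.12, whereas Kcna5 fell (-1.37 ± 0.38) along with Kcnn2. Of 21 genes of GABA, glycine, nicotinic and 5-HT3 receptors, 9 rose and 0 fell, the same counts adjusted over the list alone. Among them, Chrnb2, a nicotinic receptor subunit, rose by 1.03 ± 0.10. Of 18 ionotropic glutamate receptor genes, 5 rose and 2 fell (7 and 3 adjusted over the list alone). Grin1, the obligatory NMDA receptor subunit, rose (0.51 ± 0.09) while Grin2b (-0.75 ± 0.19) and Grin2c (-1.03) fell.

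Over the union of these lists, 42 of 124 genes rose, 10 fell and 72 did neither (48 and 15 adjusted over the list alone). In camera on the group-only fit (preset correlation of 0.01, adjusted over 30 lists), the union was higher than other genes with an adjusted p of 0.00014. With an estimated correlation its adjusted p was 0.012, and it was 0.14 with an estimated correlation and the replicate block. The sodium and calcium channel list passed at an adjusted p of 0.002 (0.045 with an estimated correlation, and 0.41 with that and the block). The potassium channel list passed at 0.0035 (adjusted p = 0.045 with an estimated correlation, and 0.30 with that and the block). The GABA, glycine, nicotinic and 5-HT3 receptor list passed at 0.00016 (adjusted p = 0.042 with an estimated correlation, and 0.30 with that and the block). The ionotropic glutamate receptor list did not pass (adjusted p = 0.99, and 0.27 with the block). At the preset without the block, 17 of 35 ways to split the libraries into groups of 4 passed at least the real 10 lists. Other splits that part all 4 pairs passed at most 7 of the 30 lists. With the block, other splits within pairs passed 5 to 10 lists against the real 13. A pass at the preset is thus weak evidence by itself, here and for the lists below. Without replicate 1 or replicate 3, 7 rather than 12 sodium and calcium channel genes rose, and fewer channel genes fell, 2 without replicate 3 or 6 and 1 without replicate 4 in that list. The falls in the glutamate receptor list numbered 1, 0 and 1 without replicates 1, 3 and 4, and those of the union 6 and 5 without replicates 3 and 4.

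**Figure D3:**
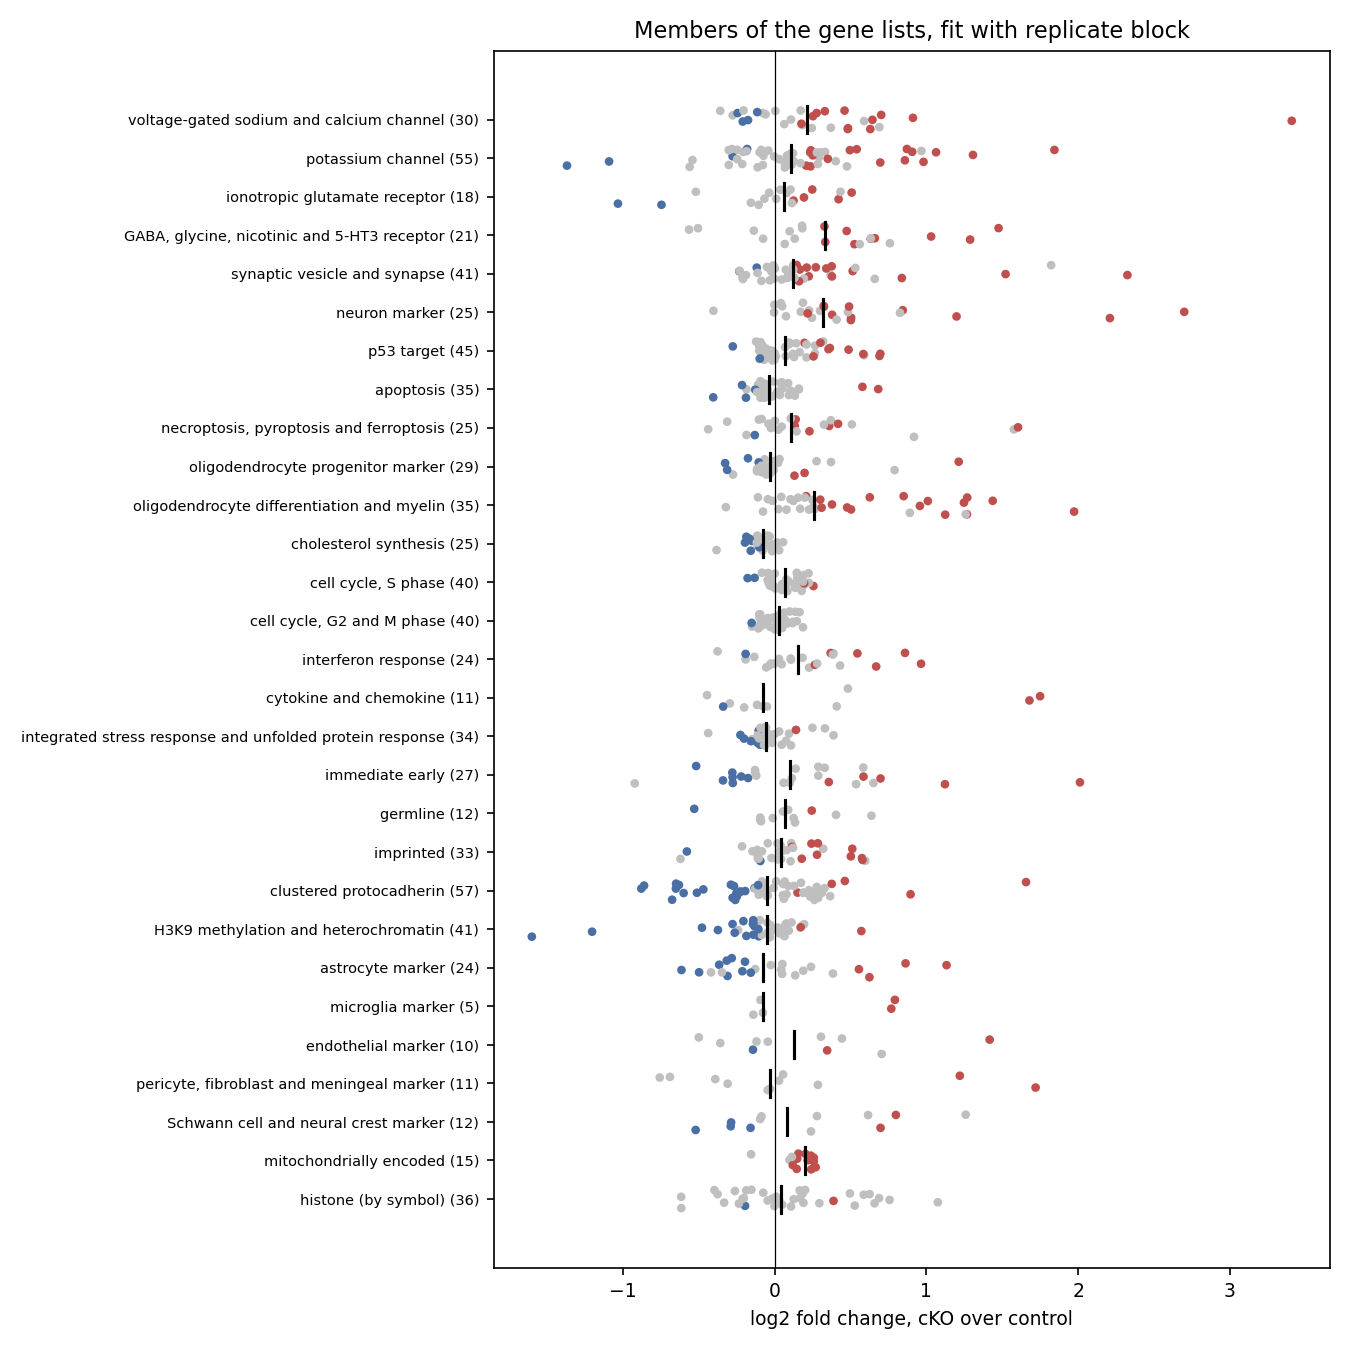
Log2 fold change of cKO over control (horizontal axis) for each tested member of 29 gene lists fixed before the data were examined, with the number tested in brackets and the union of the channel and receptor lists not drawn. Red and blue points rose and fell in the edgeR fit with the replicate block, grey points did neither, and black bars are list medians, which run from -0.08 to 0.33.

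More genes of synapses and neurons rose than fell. Of 41 synaptic vesicle and synapse genes, 13 rose, 2 fell and 26 did neither (18 and 4 adjusted over the list alone). Snap25, a core protein of vesicle fusion, rose by 1.52 ± 0.09, from 7.01 ± 1.66 to 19.9 ± 1.75 CPM (SD, n = 4). Sv2b (2.33) and Syt1 (0.84), both synaptic vesicle proteins, rose, while the inhibitory synapse adhesion gene Nlgn2 fell (-0.23). In camera the list passed at an adjusted p of 0.002 without the block, and at an adjusted p = 0.82 with an estimated correlation it did not (0.42 with that and the block). Of 25 neuron marker genes, 11 rose and 0 fell (15 and 0 adjusted over the list alone). Stmn2, a microtubule regulator of growing axons, rose by 2.70 ± 0.37, from 0.146 to 0.991 CPM, and the calcium-binding protein gene Calb1 rose by 2.21 ± 0.27. Celf4 rose by 0.84, whereas Rbfox3, which encodes the neuronal nuclear antigen NeuN, did not pass (-0.40 ± 0.17), nor did Map2 (-0.01 ± 0.03) at 970 CPM in control. The neuron list passed in camera at an adjusted p of 6.7e-07 (0.012 with an estimated correlation, and 0.30 with that and the block). Of its 25 genes, 17 already averaged at least 1 CPM in control progenitors. Without replicate 3, 7 synapse genes rose, and without replicate 1, 7 neuron markers rose.

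Cell-death genes moved in both directions and mostly by little. Of 35 apoptosis genes, 2 rose, 4 fell and 29 did neither (1 and 3 adjusted over the list alone). Bid, which links death receptors to mitochondria, rose by 0.58 ± 0.08 (6.10 to 9.12 CPM), and the initiator caspase gene Casp8 rose by 0.68 ± 0.21. The executioner caspase gene Casp6 (-0.41 ± 0.08) and Parp1 (-0.22 ± 0.03), a DNA repair enzyme and caspase substrate, fell. Camera gave the apoptosis list an adjusted p of 0.95, and 0.63 with the block. Of 45 p53 target genes, 9 rose and 2 fell, the same counts adjusted over the list alone. The death receptor gene Fas rose by 0.69 ± 0.12 and Pmaip1, encoding the BH3-only protein Noxa, by 0.49 ± 0.07. Cdkn1a, the cell-cycle inhibitor p21, was not past the threshold (0.32 ± 0.11, adjusted p = 0.114 in edgeR), nor was Mdm2 (0.07 ± 0.04). The p53 list did not pass camera on the group-only fit (adjusted p = 0.58), passed with the block at 0.032, and had an adjusted p = 0.77 with the block and an estimated correlation. Of 25 necroptosis, pyroptosis and ferroptosis genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone). They included the inflammatory caspase gene Casp1 (1.60 ± 0.26, from 0.363 CPM), the polyamine enzyme gene Sat1 (0.42 ± 0.06) and the heme oxygenase gene Hmox1 (0.36 ± 0.07). Camera gave that list an adjusted p of 0.21, and 0.094 with the block. The apoptosis counts were small and moved with single pairs, to 1 higher without replicate 1, 4 or 6 and to 2 lower without replicate 3, 4 or 6.

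More oligodendrocyte differentiation genes rose than fell, while progenitor markers moved both ways. Of 35 differentiation and myelin genes, 16 rose, 0 fell and 19 did neither (18 and 0 adjusted over the list alone). Aspa, the aspartoacylase of mature oligodendrocytes, rose by 1.97 ± 0.21, the gap junction gene Gjb1 by 1.25, and Mog, a late myelin surface protein, by 1.27 ± 0.37. Mbp, myelin basic protein, rose by 0.48 ± 0.11, with means of 103 ± 98.2 and 156 ± 151 CPM whose spread lay mainly between batches (SD, n = 4). Camera passed the list at an adjusted p of 0.0019 without the block, but adjusted p = 0.77 with an estimated correlation (0.36 with that and the block). Of 29 progenitor markers, 3 rose and 4 fell, the same counts adjusted over the list alone. The growth factor receptor gene Pdgfra fell from 969 to 773 CPM (-0.31 ± 0.03), and the matrix protein gene Matn4 rose (1.21). Olig2 (-0.06 ± 0.03), Sox10 (0.02 ± 0.04) and Cspg4 (-0.03 ± 0.04), which mark the lineage, did not pass. That list did not pass camera (adjusted p = 0.69, and 0.45 with the block), and without replicate 6 the number that fell was 7. Of 25 cholesterol synthesis genes, 0 rose and 7 fell, also adjusted over the list alone, by small amounts such as -0.20 for Lss and -0.17 for Sqle. The cholesterol list had an adjusted p of 0.058 in camera, 0.012 with the block, and adjusted p = 0.77 with the block and an estimated correlation. Its 7 falls became 4 without replicate 1 and 1 without replicate 4.

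Markers of other cell types moved unevenly. Of 24 astrocyte markers, 4 rose and 9 fell (5 and 10 adjusted over the list alone). The glutamate transporter gene Slc1a3 (-0.28 ± 0.03, from 1137 to 944 CPM) and the receptor gene Fgfr3 (-0.62) fell, while the intermediate filament gene Gfap rose (0.86 ± 0.17, from 3.18 CPM). The astrocyte list passed camera only with the block (adjusted p = 0.81 without it and 0.046 with it), and had an adjusted p = 0.42 with the block and an estimated correlation. Of 5 microglia markers tested, P2ry12 and Cd68 rose. Of 10 endothelial markers, Slco1a4 and Vwf rose and Slc2a1 fell, and of 11 pericyte, fibroblast and meningeal markers, Col1a2 (from 0.127 CPM) and Rgs5 rose. Of 12 Schwann cell and neural crest markers, 2 rose and 4 fell, among them the neuregulin receptor gene Erbb3 (-0.52). Adjusted over the list alone, the counts were 2 and 0 for microglia, 5 and 1 for endothelium, 2 and 0 for pericytes and 2 and 5 for Schwann cells. None of these last 4 lists passed camera, with adjusted p from 0.72 to 0.99 without the block and from 0.52 to 0.80 with it. The counts for these 4 lists rest on few genes and reached 0 higher without replicate 1 for microglia and endothelium, and 0 higher without replicate 6 for endothelium.

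Most genes of the gamma family of clustered protocadherins, cell-surface adhesion proteins chosen from tandem promoters, fell. Of 57 clustered protocadherin genes on chromosome 18, 5 rose, 20 fell and 32 did neither (9 and 20 adjusted over the list alone). In the gamma family, 18 of 22 fell and 0 rose, with a median of -0.27, led by Pcdhgb4 (-0.88 ± 0.06, from 31 to 17 CPM), Pcdhga2 (-0.86) and Pcdhga3 (-0.68). In the alpha family, 2 of 13 rose, including Pcdhac1 (0.90 ± 0.12), and in the beta family 3 of 22 rose and 2 fell. Members of the alpha family share constant exons, as do those of the gamma family. Counting could split their reads, so single alpha and gamma members are uncertain. The list had an adjusted p of 0.058 in camera, 8e-04 with the block, and adjusted p = 0.42 with the block and an estimated correlation. Without replicate 1 or 4, 13 and 12 genes of the list fell.

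**Figure D4:**
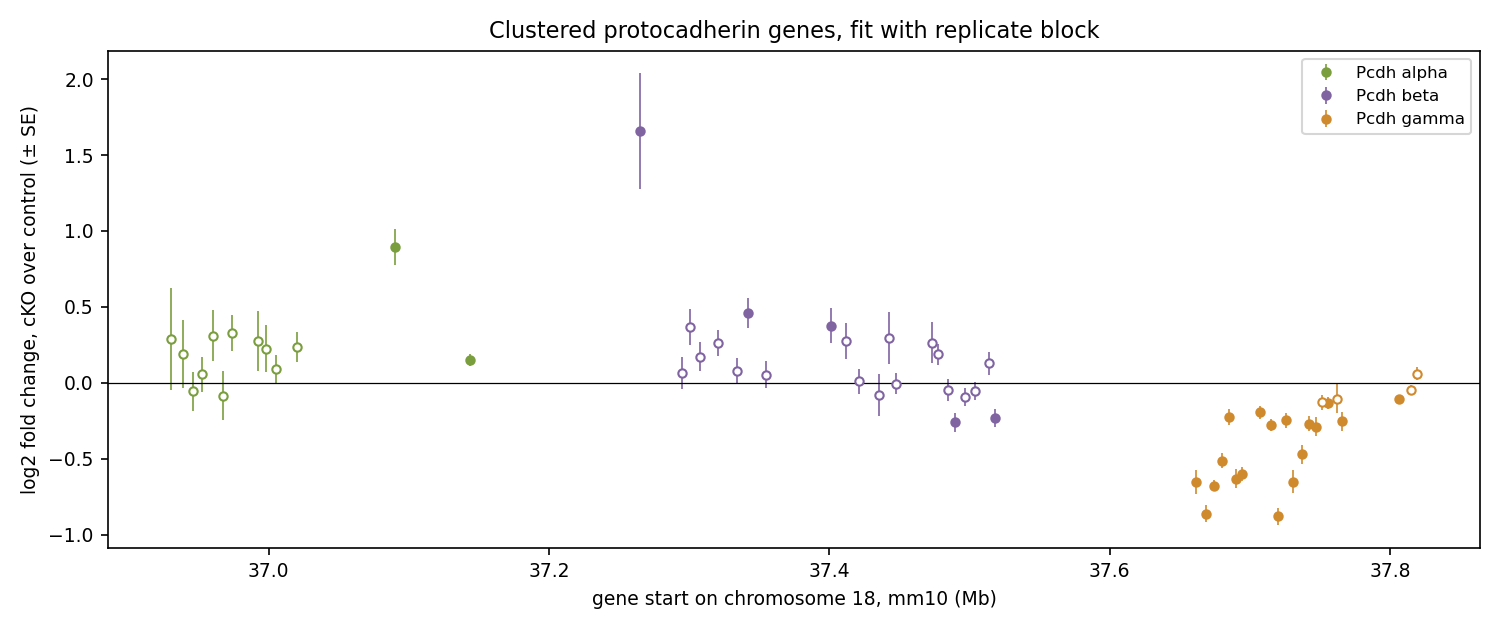
Log2 fold change of cKO over control ± SE (vertical axis) against gene start on chromosome 18 in mm10 (horizontal axis, Mb) for the 57 clustered protocadherin genes tested, from the edgeR fit with the replicate block. Filled circles passed an adjusted p of 0.05 and open circles did not; 18 of the 22 gamma genes (orange) fell, while 2 of 13 alpha (green) and 3 of 22 beta genes (purple) rose.

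In a list on H3K9 methylation and heterochromatin, which holds methyltransferase and demethylase genes alike, more genes fell than rose. Of 41 genes of H3K9 methylation and heterochromatin, 15 fell, Ehmt1 and Ehmt2 included, 2 rose and 24 did neither (17 and 4 adjusted over the list alone). The demethylase gene Kdm3b (-0.48), the chromodomain gene Cdyl (-0.37) and the methyltransferase gene Setdb1 (-0.14) fell, and Zfp518a rose (0.57). Camera passed the list as lower at an adjusted p of 0.00068, but that rests on the 2 targeted genes, whose fall the design sets. Without them, 13 of 39 fell and 2 rose, and camera gave an adjusted p of 0.086, 0.016 with the block, and 0.41 with the block and an estimated correlation. With them, 8 genes of the list fell without replicate 4. Of 33 imprinted genes, 9 rose and 2 fell (9 and 3 adjusted over the list alone), with Zim1 at 0.58 and Peg3 at 0.28. Of 12 germline genes, Taf9b rose and Stag3 fell, also adjusted over the list alone. Of 36 histone genes taken by symbol, most of them replication-dependent, H2bc6 rose and H1f10, a replication-independent linker histone gene, fell, and adjusted over the list alone only 1 passed, lower. Camera gave these last 3 lists an adjusted p of 0.35, 0.95 and 0.58, and 0.12, 0.67 and 0.68 with the block. Imprinted genes that rose numbered 4 without replicate 1.

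Few cell-cycle genes moved. Of 40 S phase genes, 2 rose (Ccne2 and Prim1) and 2 fell (E2f8 among them), and of 40 G2 and M phase genes 1 fell (Tacc3, -0.15). Adjusted over the list alone, 0 passed in either list. Camera gave adjusted p values of 0.96 and 0.95, and 0.16 and 0.99 with the block. These counts depended on 1 batch. Without the pair of replicate 6, 14 G2 and M phase genes and 7 S phase genes fell, while without replicate 3 or 4 none of either list passed in the blocked edgeR fit.

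Stress and signalling genes were mixed. Of 24 interferon response genes, 6 rose and 1 fell, the same counts adjusted over the list alone, with the guanylate-binding protein gene Gbp7 at 0.96, Ifit3 at 0.86 and the RNA sensor gene Ifih1 at 0.67. Camera passed the list at an adjusted p of 0.02, with adjusted p = 0.76 with an estimated correlation and 0.081 with the block. Of 34 genes of the integrated stress and unfolded protein responses, 1 rose and 7 fell (1 and 8 adjusted over the list alone), by small amounts such as -0.23 for the serine synthesis gene Phgdh. Of 27 immediate early genes, 5 rose and 7 fell (7 and 7 adjusted over the list alone). The activity-dependent genes Npas4 (2.01 ± 0.32, from 0.161 CPM) and Arc (1.12 ± 0.11) rose, and the phosphatase gene Dusp1 fell (-0.34). Of 11 cytokine and chemokine genes, Ccl2 (1.75 ± 0.43, from 0.159 CPM) and Il34 (1.68) rose and Tgfb2 fell, also adjusted over the list alone. Camera gave these 3 lists an adjusted p of 0.37, 0.99 and 0.99, and 0.16, 0.67 and 0.96 with the block. Of 15 mitochondrially encoded genes, 12 rose and 0 fell (13 and 1 adjusted over the list alone), by small amounts such as mt-Co1 at 0.26 ± 0.04. The mitochondrial list passed camera at an adjusted p of 0.0012, but adjusted p = 0.76 with an estimated correlation (0.42 with that and the block). Single pairs moved several of these counts. Without replicate 3, 7 mitochondrial genes and 3 interferon genes rose; the stress response falls numbered 2, 3 and 2 without replicates 1, 3 and 4, and the immediate early falls numbered 3 and 4 without replicates 3 and 4.

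Over the 30 lists, camera on the group-only fit passed 10, 9 of them higher, and 5 of these passed with an estimated correlation. Without the 2 targeted genes in the lists, the 1 lower list no longer passed. With the block 13 passed, 9 higher and 4 lower, and 0 passed with the block and an estimated correlation. In that last setting the union and the potassium channel list did not pass although their estimates (0 and -0.01) were not above the preset. In fry with the block, which tests a list by itself and not against other genes, 13 passed, 10 higher and 3 lower. They included the glutamate receptor (adjusted p = 0.0054), interferon (0.0079), necroptosis (0.018), stress response (0.024) and microglia (0.049) lists, which did not pass camera with the block. With the block, camera but not fry passed the synapse (fry adjusted p = 0.056), mitochondrial (0.056), astrocyte (0.077), cholesterol (0.21) and p53 (0.25) lists. In the group-only edgeR fit, Ehmt1 and Ehmt2 were the list members past the threshold over all genes. Adjusted over the list alone in that fit, 2 sodium and calcium channel genes, 2 synapse genes and 2 neuron markers rose, 1 protocadherin gene rose and 3 fell, and 1 heterochromatin gene rose and 3 fell. Median, mean and camera direction differed in sign for the glutamate receptor, progenitor, cytokine, astrocyte, microglia, pericyte, Schwann cell and G2 and M phase lists, all with medians between -0.08 and 0.08. List counts of 5 or fewer genes, those of the cell-cycle and progenitor lists apart, moved by at most 3 genes when the pair of 1 replicate was left out; the microglia list was not counted without replicate 4 or 6, where fewer than 5 of its genes were tested.

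Since direction varied with level, list counts were also set against random genes of the same 20 expression bins, by mean CPM over both groups. This test was added after the results were seen (permutation p from 10000 draws, adjusted over 60 counts). More genes rose than in such draws for the union of channel and receptor lists (42 against a mean of 13), its sodium and calcium, potassium and GABA to 5-HT3 receptor parts, and the synapse (13 against 4.3), neuron (11 against 2.4), differentiation (16 against 3.5), imprinted (9 against 3.3) and mitochondrial (12 against 1.3) lists. More fell for the protocadherin (20 against 5.1), heterochromatin (15 against 7.6, the targeted genes included) and immediate early (7 against 2.3) lists. The falls of cholesterol (7 against 5.5) and stress response genes (7 against 5.3) did not pass, with adjusted permutation p of 0.68 and 0.67. These draws treat genes as independent, which genes of a list are not.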

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

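The rule for finding single libraries apart from the rest was planned; some of the genes it was applied to were named because of their rank in the results. For each group and each named gene, and for library total, the share of counts from the most abundant gene and the mitochondrial share, the gap between the most extreme library and its nearest neighbour was divided by the range of the 4 libraries (log2 CPM for genes), and values above Dixon's critical value for 4 samples at the 95% level were listed. Of 274 groups, 9 passed, with ratios of 0.83, 0.832, 0.85, 0.851, 0.886, 0.92, 0.92, 0.924 and 0.928, fewer than the 13.7 that chance gives at 1 in 20.

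Piezo2 in cKO replicate 4 was lowest (0.622 against 1.29 to 1.43 in the others; ratio 0.83). Calb1 in cKO replicate 3 was highest (0.985 against 0.182 to 0.243; ratio 0.924). Stmn2 in control replicate 4 was lowest (-4.25 against -2.33 to -1.99; ratio 0.85). Mvk was highest in replicate 4 of both groups, in control (6.25 against 5.78 to 5.86; ratio 0.832) and in cKO (6.08 against 5.61 to 5.64; ratio 0.928). Tgfb1 in control replicate 1 was highest (-1.36 against -1.73 to -1.70; ratio 0.92), and so was Cxcl12 in the same library (1.74 against 0.342 to 0.55; ratio 0.851). The mitochondrial gene mt-Nd4 in cKO replicate 3 was lowest (10.9 against 11.2 in the others; ratio 0.92).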

How the results depend on the processing

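The combinations of the replicate block with other scaling, filters, limma-voom, a left-out ribosomal RNA gene, an estimated correlation and fry, the lists without the targeted genes, and the results on changes of at least 2-fold, were tests chosen only after the results were seen; the other settings were planned. The count of genes changed depended most on the block. The group-only edgeR fit called 3 genes (1 higher, 2 lower), and the fit with the replicate block called 3706 (1817 higher, 1889 lower), since the block removes the spread between batches from the error. Without the block, RLE factors, upper-quartile factors and no filter stayed within 1.5 times of 3 genes, the stricter filter called 7 genes (5 higher), limma-voom 9 (7 higher), and DESeq2 191 (157 higher, 34 lower); the cause was not tested. Leaving out 1 library of the group-only fit gave 1 to 5 genes, 0 to 3 higher and 1 to 2 lower. The extremes were 5 genes without control replicate 1 and 1 gene without control replicate 4 or control replicate 6.

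With the block, the other settings gave counts of the same order as the replicate block. RLE factors called 3758 genes (1780 higher, 1978 lower), upper-quartile factors 3574 (2021 and 1553), the stricter filter 3381 (1641 and 1740), limma-voom 3849 (1864 and 1985), DESeq2 3009 (1464 and 1545), and the fit without CT010467.1 3624 (1888 and 1736). Genes shared with the blocked edgeR call numbered 3667, 3370, 3274, 3665, 2921 and 3547 in that order. Leaving out a pair lowered the counts, with fewer samples: 2367 without replicate 1 (1224 higher, 1143 lower; 2232 shared with the full blocked call), 2102 without replicate 3 (1127, 975; 1992 shared), 2118 without replicate 4 (1208, 910; 2008 shared) and 3432 without replicate 6 (1702, 1730; 2872 shared). The share of calls that were higher ran from 47.4% to 57.0%, against 49.0%. Changes of at least 2-fold numbered 424 and fell to 178 with the stricter filter, which tests fewer genes of low level; 90.8% of the 424 and 89.6% to 92.7% under the other block settings were upward. Over the 3 scalings the median log2 fold change of all genes with the block ran from -0.01 to 0.01.

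Ehmt2 kept its call under all 26 settings (log2 fold change -1.66 to -1.55). Ehmt1 kept it under 24 of 26 (-1.25 to -1.14) and lost it without control replicate 4 (-1.22, adjusted p = 0.0503) and without control replicate 6 (-1.18, adjusted p = 0.0506) in edgeR, and over the single libraries left out its change ran from -1.25 to -1.14. All 20 genes named as most changed passed in every block setting run. Of 103 named genes past with the block, 75 did. Over all named genes and settings against the group-only fit, 2203 values kept direction and side of the threshold, 1043 (112 genes) passed only under the alternative, and 9 (2 genes) no longer passed. Of the camera list counts, 10 lists passed with a preset correlation, 5 with an estimated correlation and 4 with fry. With the block 13 passed, 13 with fry and 0 with an estimated correlation. For the union of channel and receptor lists and the potassium channel list, the correlation estimated with the block was 0 and -0.01. These values are not above the preset of 0.01, so a higher correlation does not account for the loss of these lists. Other lists, such as the mitochondrial list (0.66), had higher estimates, and the cause was not tested further. Without the targeted genes in the lists 9 passed, and 13 with the block. Other scaling, filters and left-out libraries stayed within 1.5 times.

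Direction reversed in 11 genes, none past the threshold in those fits, all but 1 value in the group-only fit with 1 library left out. The ranges over the left-out libraries were -0.61 to 0.02 for Pdgfra (0.0186 without control replicate 3), -0.445 to 0.024 for E2f8, -0.0928 to 0.563 for Ccne2, -0.111 to 0.468 for Prim1, -0.368 to 0.0355 for Tacc3, -0.442 to 0.0513 for Plk1, -0.347 to 0.125 for Hjurp, -0.424 to 0.157 for Cdc20, -0.588 to 0.105 for Cxcl12, -0.66 to 0.00999 for Slc7a10 and -0.403 to 0.152 for Gpr34. Gpr34 was also 0.185 with the replicate block without replicate 1. The causes were not tested. For genes under 1 CPM in control libraries, 3853 of the 18102, depth limits precision: over the 4 control libraries Serpinb1a had 87 counts in all and Mlip 20.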

Other observations

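The tests of the p53 response, neuron markers, position in the protocadherin cluster and paralogues among neighbours were chosen only after the results were seen, as were the stricter level rules for changes of at least 2-fold and the lists of dense-core granule and axon guidance genes, on which no test is given. The tests of other sample splits were planned. Those of low counts, the summed protocadherin counts and chromosomal neighbours were set before their own values were seen, but on patterns found in the results, such as changes of at least 2-fold.

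More genes of dense-core granules, the vesicles that store neuropeptides and hormones, rose than fell in cKO. In a list drawn up after the data were seen, 11 of 22 rose and 0 fell with the replicate block, or 50% against 10% of all genes tested and 11% on average in random genes of the same expression bins. The 11 included the granins Scg2 (1.85 ± 0.19 SE, from 3.82 to 12.8 CPM) and Chga (0.98 ± 0.12), the neuropeptide precursor Vgf (1.41 ± 0.16), and the granule membrane protein Ptprn (1.54 ± 0.08, from 15.4 to 44.3 CPM). The prohormone convertase genes Pcsk1 (1.23 ± 0.36) and Pcsk2 (0.61 ± 0.10) rose as well. The list was drawn up knowing that several of its genes had changed, so these shares test nothing. Such genes are typical of neurons as well, and neuron markers and synapse genes also rose more often than they fell, so what is said of neurons in the cKO cultures below applies here too.

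Axon guidance genes more often fell. Of 65 genes in a list also drawn up afterwards, 17 fell and 9 rose with the block, the falls being 26.2% against 10.4% of all genes tested and 12% on average in random genes of the same expression bins. This list too was drawn up with the calls known, so these shares test nothing. Ntn1, a secreted guidance cue, fell from 143 to 83.4 CPM (-0.78 ± 0.04), and Sema6d (-0.60 ± 0.03), Ephb1 (-0.61 ± 0.07), Rgma (-0.52 ± 0.03) and Plxnb1 (-0.43 ± 0.03) fell. Sema3d (0.93 ± 0.12), Epha3 (0.73 ± 0.13) and Slit2 (0.45 ± 0.06) rose.

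Changes of at least 2-fold went mostly upward with the block, 385 against 39, and noise at low counts might give such a bias. Among the 29 such genes with a mean of at least 10 CPM, 89.7% were upward (exact 95% interval 72.6% to 97.8%), which argues against low counts as the whole cause, although less firmly under stricter rules. With each group mean at least 10 CPM, 14 of 17 were upward (56.6% to 96.2%), or 14 of 15 (68.1% to 99.8%) without Ehmt1 and Ehmt2, whose fall the design sets. With the control mean alone at least 10 CPM, which favours falls, it was 14 of 18 (52.4% to 93.6%). These intervals treat genes as independent, which genes measured in the same libraries are not. A p53 response to Cre recombinase was weighed too. Of 45 p53 targets, 9 rose and 2 fell, and 0 rose at least 2-fold. An interval of the same kind allows a share of up to 7.9%. The test was chosen after the results were seen and cannot exclude a p53 response of smaller size. Other effects of Cre cannot be separated from loss of Ehmt1 and Ehmt2, since every cKO library and no control library had the enzyme. Loss of a repressive methyltransferase pair stays an open, untested explanation.

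More neuron and synapse genes rose than fell with the block (11 and 0 of 25 neuron markers, 13 and 2 of 41 synapse genes), although neither list passed camera with the block and an estimated correlation (adjusted p = 0.30 and 0.42). A few neurons in the cKO cultures might account for the rises, although immunopanning would remove many. Of 4 pan-neuronal markers at a low level in control, 1 rose, Stmn2 (2.70 ± 0.37 SE), while Nefh (0.48 ± 0.31), Snhg11 (0.41 ± 0.18) and Rbfox3 (-0.40 ± 0.17) did not pass. Neurons would add to a different baseline for each gene, and the highest mean of the 4 in cKO was 1.44 CPM, so these values do not decide whether neurons were present. Expression of neuronal genes in progenitors stays open too, as untested.

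In the gamma protocadherins (chromosome 18, 37661793 to 37841873), reads might only have moved between members that share exons. The summed count of the 22 genes fell (log2 fold change -0.18 ± 0.03 SE with the block, and -0.35 without the abundant Pcdhgc3), with losses of 250 CPM against gains of 1.18, which argues against that. The fall was larger toward the first promoters of the cluster. Across the 22 genes, log2 fold change rose with start coordinate (Spearman rho 0.76, Pearson r 0.74, permutation p = 1e-04), and genes are not independent replicates. A graded change along the cluster is a hypothesis, and division of shared reads by the counting stays open as a part of the gradient.

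Genes at least 2-fold higher were more often chromosomal neighbours than permutation within expression bins gives. Such permutation does not keep variation that neighbours may share apart from the cKO. Neither fallen genes nor other splits were counted in this way, so the excess cannot be tied to the cKO. There were 24 non-overlapping neighbouring pairs, against a mean of 6.6 in 10000 permutations within expression bins (p = 1e-04, the smallest they can give). Examples are Ptprn with Resp18, Slpi with Matn4 and Serpinb1a with Serpinb9. Without pairs whose symbols share their first 4 characters, 20 pairs remained against a mean of 6.2 (permutation p = 1e-04). That rule still counts Gbp9 with Gbp6, and it cannot judge gene models such as Gm5067 with Gm7361. Paralogues alone may thus not account for the excess, but they were not fully removed. A candidate explanation is release of repression over short domains, which these counts cannot test. Read-through from 1 gene into the next is another. Of the 24 pairs, 17 lie on the same strand, but the share among all neighbours was not taken, so this decides nothing.

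Other splits of the libraries bear on the counts. In the group-only fit, 2 of the 35 splits, the real one included, gave as many genes as the real 3. The other was the split of replicates 1 and 3 against 4 and 6, which called 5751 genes and points to a structure by batch. Its highest counts were 2893 for either direction, with 2 splits as large for each. That split keeps every pair together, unlike the real one, so the share over 35 splits cannot decide on chance. Among the 8 splits that part all 4 pairs, the 7 others gave 0 genes and at most 7 lists, but 8 splits are too few for a share under 0.05. For gene lists, 17 of the 35 splits gave at least the real 10 (highest other 15). The others among these 17 kept some or all pairs together, and chance was not excluded for the group-only list count. With the block there are only 8 splits within pairs, too few for a share under 0.05. The real split gave 3706 genes, 424 changes of at least 2-fold and 13 lists. It alone gave counts this large (1 of 8 each), against a highest other of 0, 0 and 10. Each of the 7 others passed at least 5 lists with the block. At an unadjusted p under 0.05 in edgeR, the real split had 6218 genes and the 7 others 107 to 705.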
